A study of Homo sapiens with 4 samples.

How the data were processed

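Total RNA of sorted CIN612 9E cells was amplified with T7-based linear amplification and labelled with Cy3 for one-colour Agilent hybridisation, per the labels' protocols. The deposited values are linear probe intensities, 1 column per array. The scanner software, background correction and normalization are not given in the sources used here. No value was negative or missing, the lowest value per array lay between 2.56 and 3.53, and medians and 75th percentiles differed between arrays, so the intensities were treated as unscaled. No flags for outlier spots, saturation or signal above background were used, since the table holds intensities only. Dim signal therefore has no detection limit here, and a fold change against a value near the bottom of an array depends on that array's low-end offset. All 4 value columns were matched to a sample, and 0 columns of other samples were present.

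The table identifies probes by IDs of 4 series (18435 in series 23, 12727 in series 24, 6044 in series 32 and 5259 in the HS series). What the series numbers stand for is not given in the sources used here. The reference table of RefSeq genes (GRCh38.p14) held 0 of the 42465 IDs, so no probe was given a gene name. Every probe was therefore tested, in place of the planned single value per gene. The planned check of the CEACAM genes against the labels, and the planned tests of 29 gene lists with camera and fry, were not run. Without those genes the values cannot decide between the titles and the conflicting CD66 characteristic.

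Intensities were log2-transformed and each array's 75th percentile was subtracted, as fixed before the data were examined for the case of unscaled linear values. CD66High was compared with CD66Low in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, all 4 arrays in one fit, two-sided, and Benjamini-Hochberg adjustment over all probes with a threshold of 0.05. Intervals are 95% intervals from the moderated fit. Probes were called bright or dim by whether their mean over the 4 arrays lay above the median of all probes. The descriptive count of probes at least 2-fold apart in both sets uses the difference of the 2 arrays within each set.

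The labels number the arrays of each sorted group 1 and 2, give same-numbered samples one prefix, and the series speaks of 2 sets of experiments. Same-numbered arrays were therefore taken as pairs, and the paired fit has the number as a replicate block. As a check, the deviation of same-numbered arrays from their group means correlated at 0.10 across all probes and at 0.28 across bright probes. The labels do not say that both sorted groups of a set came from the same culture. The series describes the sets as biological replicates, and the p-values rest on that description. For technical replicates they would measure only the spread between these samples. No array pair was close enough to be one hybridisation deposited more than once. The SD of the log2 difference over bright probes was at least 0.231 for every pair.

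The rule for named probes, fixed before the data were examined, took the largest differences among probes past the threshold and filled up with the largest differences among probes for which both arrays of one group lay on one side of both arrays of the other. It was limited here to 2 probes in each direction because IDs carry no gene names. Simulated arrays had the real means, the spread fitted without the replicate block and no difference between the sets. The test was tried on them with 42465 probes in the fit, 200 of them bright probes changed by 2-fold, 4-fold or 8-fold. It recovered 0%, 95.5% and 98.0% of the changed probes, with 0, 10 and 5 false calls, and made 0 calls on arrays with no change.

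The settings changed one at a time, as fixed before the data were examined, were the replicate block, quantile normalization, median centring, leaving out the dimmest 25% or 50% of probes, no trend in eBayes, a test against a 1.5-fold minimum, leaving out each array and the groups of the CD66 characteristic. No scaling, cyclic loess, an offset of 50 added before the log and the crossed groups were added after seeing the data. So were the block together with other scalings or with the 50% filter, and the 50% filter together with quantile normalization or cyclic loess. The 50% filter and cyclic loess for the 2-fold count were also added then. The planned change of the rule for several probes per gene does not apply to a test of every probe.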

Results

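Gene expression was profiled on 4 one-colour arrays of CIN612 9E cells, a keratinocyte line grown out of a cervical precancer that maintains human papillomavirus genomes. The cells were cultured on mitomycin-treated mouse fibroblast feeders and separated with beads carrying an antibody against CD66, a group of cell surface glycoproteins of the carcinoembryonic antigen family. The single comparison set cells sorted as CD66High (n = 2) against cells sorted as CD66Low (n = 2), 1 array of each in each of 2 sets of experiments. It asks which transcripts distinguish the CD66High cells of a precancer line from the CD66Low cells grown with them. The series describes the sets as biological replicates. The titles, descriptions and source names gave these groups, whereas the characteristic for CD66 expression called both arrays of set 1 high and both arrays of set 2 low. The groups of the 3 labels that agree were used.

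Each array held an intensity for 42465 probes. The median intensity was 135.2 and 128.7 on the CD66High arrays of sets 1 and 2, and 142.2 and 121.7 on the CD66Low arrays. The 75th percentile was 1181 and 1162 on the CD66High arrays and 1310 and 1115 on the CD66Low arrays. The number of arrays limits the precision. Neither the value table nor the reference pairs the probe IDs with genes, so changes are given by probe, and neither the CEACAM genes of the sorted antigen nor the 29 gene lists fixed in advance were examined.

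The 4 arrays were close to each other, with Pearson correlations of log2 intensity between 0.990 and 0.993 across probes. Among the 21232 bright probes, those with a mean signal above the median of all probes, the CD66High and CD66Low arrays of one set differed less than replicates of one sorted group did. The SD of the log2 difference over these probes was 0.263 between CD66High and CD66Low cells in set 1 and 0.231 in set 2. It was 0.285 between the 2 CD66High arrays and 0.308 between the 2 CD66Low arrays. For the pairs that differed in both set and sorted group it was 0.263 between the CD66Low array of set 1 and the CD66High array of set 2, as large as within set 1, and 0.322 between the remaining 2 arrays. Among the 21233 dim probes it ranged from 0.587 for the sorted groups of set 1 to 0.724 for those of set 2.

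One transcript probe was higher in CD66High cells and none was lower when all 42465 probes were tested without the replicate block. GT_44k_23_P62709 rose 5.63-fold on the scaled log2 values, and its unscaled intensity was 1096 ± 73.8 (SD, n = 2) in CD66Low cells and 5980 ± 390 (SD, n = 2) in CD66High cells. Its log2 difference was 2.49 with a 95% interval from 2.22 to 2.77 and a limma adjusted p of 0.0268, and it was 2.60 in set 1 and 2.39 in set 2. Its mean signal lay at the 82.6th percentile of all probes. At an unadjusted p under 0.05, limma placed 1702 probes, 1478 of them higher and 224 lower in CD66High cells, against 2123 that chance gives over all probes in the absence of other differences. That fit ignores the pairing and leaves differences between the sets in its residual spread. A count under 2123 therefore does not show that the sorted groups are alike. The adjusted p of GT_44k_23_P62709 was 0.332 after quantile normalization and 0.0632 after cyclic loess, and it was 0.307 without the CD66High array of set 1 and 0.586 without that of set 2. Its limma adjusted p was 2.79e-05 without the CD66Low array of set 1 and 4.22e-05 without that of set 2, in fits that rest on a lone CD66Low array and made 325 and 147 calls.

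With the set of experiments as a replicate block, 27 probes rose and 2 fell in CD66High cells. GT_44k_23_P62709 was among them with a limma adjusted p of 0.00058. Of these 29 probes 26 were bright, and 25 of those 26 were higher in CD66High cells. At an unadjusted p under 0.05 the paired fit placed 2962 probes, 2332 higher and 630 lower, where chance gives 2123. Under quantile normalization the paired limma fit called 0 probes, with 1997 at an unadjusted p under 0.05, and under cyclic loess it called 12, with 2417 at that level. When the dimmest 50% of probes were left out, the unpaired fit called 3 probes, each higher in CD66High cells and each also called by the paired fit over all probes. GT_44k_23_P62709 was one of the 3. On the scaled values the second was 4.09-fold higher, with unscaled mean intensities of 7094 and 1788, and the third was 3.72-fold higher, with unscaled mean intensities of 356.3 and 98.9. Over the bright probes, the unpaired fit called 2 probes after quantile normalization and 2 after cyclic loess, all higher in CD66High cells. The lowest limma adjusted p was 0.0376 and 0.0106.

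Of the bright probes, 16 were at least 2-fold higher in CD66High than in CD66Low cells in both set 1 and set 2, and 1 was at least 2-fold lower in both. A further 14 bright probes were at least 2-fold apart in opposite directions, 10 of them higher in CD66High cells in set 1 and lower in set 2, and 4 the other way round. The 16 were between 2.15-fold and 5.63-fold higher on average, with a median log2 difference of 1.62 and mean intensities between 227.6 and 4441. The 1 lower probe had a log2 difference of -1.36. Each of the 17 had an unadjusted limma p under 0.05, but only GT_44k_23_P62709 passed after adjustment over all probes without the block, while all 17 passed with it. The 17 were picked by these same differences, so small p-values were likely for them and are no separate support. The passes with the block depended on the settings: 9 of the 17 remained when the dimmest 50% of probes were left out, 11 after cyclic loess and 0 after quantile normalization, where the lowest limma adjusted p of any probe was 0.924. The 16 carried IDs of 3 of the array's 4 ID series, 13 of them in series 23, 1 in series 24 and 2 in the HS series. The split between 16 higher and 1 lower was the same after quantile normalization and after cyclic loess.

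**Figure D1:**
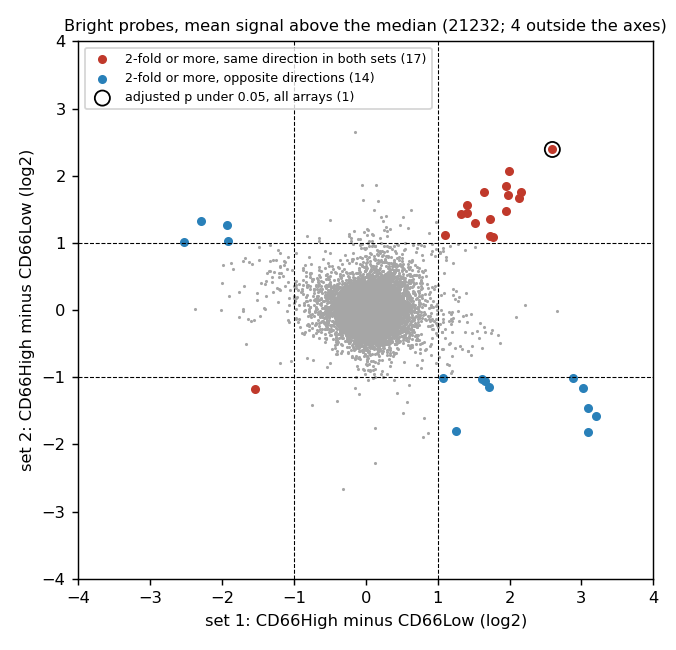
Each point is 1 of the 21232 bright probes, placed by its log2 difference between CD66High and CD66Low cells in set 1 (x axis) and in set 2 (y axis); dashed lines mark 2-fold, 4 probes lie outside the axes, red points are at least 2-fold apart the same way in both sets, blue points at least 2-fold apart in opposite directions, and the ring marks the probe past the adjusted threshold. Of the red points 16 lie at the upper right and 1 at the lower left, and of the 14 blue points 10 lie at the lower right and 4 at the upper left.

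Over all probes, 317 were at least 2-fold higher and 50 at least 2-fold lower in CD66High cells in both sets, and 350 of these 367 were dim. The size of that excess of higher probes depended on the scaling: quantile normalization gave 152 higher and 107 lower, and cyclic loess 229 higher and 65 lower. Other splits of the same arrays gave similar numbers of bright probes at this fold, in both directions. Of the bright probes, 12 were at least 2-fold higher and 8 at least 2-fold lower in set 1 than in set 2 within both sorted groups. With groups crossed between the sets, 10 were higher and 9 lower within both sorted groups. Paired within each set, the same crossed groups gave the 10 and 4 bright probes that differed in opposite directions. Between set 1 and set 2 across the sorted groups, 14 were higher and 7 lower in set 1.

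Most probes differed by less than 2-fold, and the differences of the 2 sets were close to uncorrelated. Across the bright probes, which are not independent replicates, the log2 differences in set 1 and set 2 had a Pearson's r of -0.03 and a Spearman's rho of -0.03. The difference had the same sign in both sets for 48.4% of these probes, where chance gives 50%. The 95% interval of the difference lay within 2-fold either way for 20584 of the 21232 bright probes (96.9%) and for 10699 of the 21233 dim probes (50.4%). The median margin of that interval to either side was 0.35 on the log2 scale for bright probes and 0.78 for dim ones. In simulated arrays of the same 42465 probes, the unpaired test recovered 0 of 200 bright probes changed 2-fold, 191 of 200 changed 4-fold and 196 of 200 changed 8-fold. It made 0, 10 and 5 false calls. The paired fit recovered 0, 188 and 199 of 200, with 1, 18 and 7 false calls, so that neither fit found simulated changes of 2-fold. The simulated arrays held no difference between the sets and took their spread from the unpaired fit. They therefore do not give the power of the paired fit on the real arrays, where its bright calls went down to 1.83-fold. The 200 planted changes also ease the adjusted threshold. The real bright probe that was 4.09-fold higher had an unpaired limma adjusted p of 0.0724 over all probes.

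More probes had a small unadjusted p between the sets of experiments than between the sorted cells. Grouping the arrays by set, which is also the grouping that the CD66 characteristic gives, placed 5101 probes at an unadjusted limma p under 0.05, against 1702 for the groups of the titles and 1202 for the remaining way of splitting the 4 arrays. No probe passed the adjusted threshold between the sets in the unpaired fit, where the lowest limma adjusted p was 0.228. In fits with the other factor as a block, 5695 probes differed between the sets and 2962 between the sorted groups at an unadjusted p under 0.05, and 57 and 29 passed the limma adjusted threshold. The numbers past that threshold turned on the scaling, with 0 and 12 under cyclic loess and 0 and 0 under quantile normalization.

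**Figure D2:**
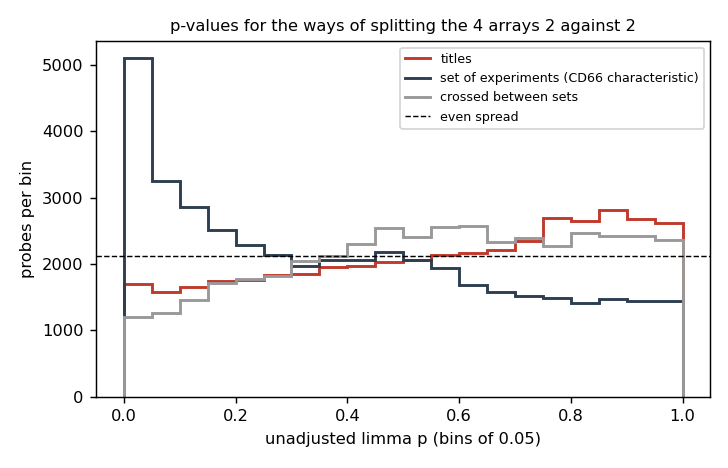
The number of probes (y axis) in each bin of 0.05 of the unadjusted limma p (x axis) is drawn for the 3 ways of splitting the 4 arrays 2 against 2, with a dashed line at an even spread. The split by set rises to 5101 probes in the lowest bin, while the split by the titles (1702) and the crossed split (1202) stay under the even spread there.

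The remaining probes named by the fixed rule had the largest differences, short of the threshold, among probes whose sorted groups did not overlap. GT_44k_23_P433586 had intensities of 3.59 and 5.57 on the CD66High arrays of sets 1 and 2, near the lowest value of those arrays (3.53 and 2.56), and 113.3 and 83.7 on the CD66Low arrays. Its log2 difference was -4.40 with a limma adjusted p of 0.130, and 0.0060 with the replicate block, but its size depends on values at the bottom of the arrays: with an offset of 50 added before the log it was -1.39 with a limma adjusted p of 0.0027. The other two were set by 1 array each. GT_44k_24_P257478 read 7944 on the CD66High array of set 2 and between 25.2 and 32.7 on the other arrays, so that its log2 difference of 4.25 ± 2.31 (SE) was made up of 8.24 in set 2 and 0.27 in set 1. GT_44k_23_P23171 read 22881 on the CD66Low array of set 2 and between 95.7 and 122.0 on the other arrays, with log2 differences of -7.96 in set 2 and -0.04 in set 1, and the SE of their mean was 2.26.

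**Figure D3:**
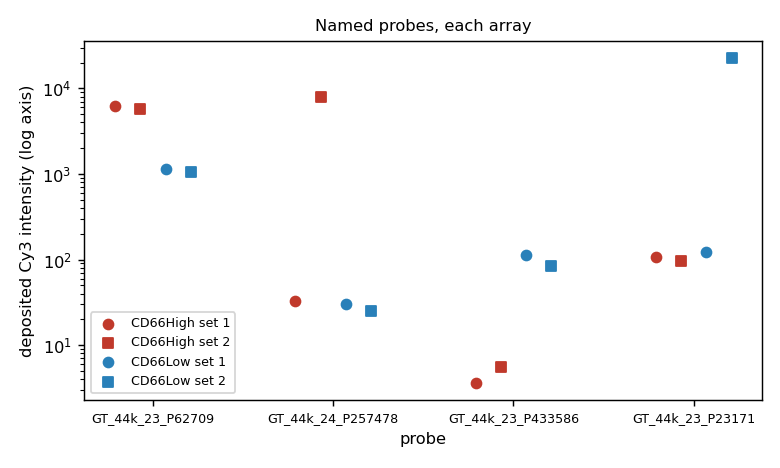
The deposited Cy3 intensity (y axis, log scale) of the 4 named probes (x axis) is shown for each array, with red for CD66High, blue for CD66Low, circles for set 1 and squares for set 2. GT_44k_23_P62709 separates the sorted groups in both sets, while GT_44k_24_P257478 and GT_44k_23_P23171 each have a single array far above the other 3.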

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

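The count of 1 probe past the adjusted threshold (1 higher, 0 lower) moved with most settings, and the log2 difference of GT_44k_23_P62709 did not: it stayed between 2.44 and 2.55 whenever the titles' groups were kept, and its call was lost under 9 of 19 alternatives. Those 9 include the groups of the CD66 characteristic and the crossed groups, which no longer compare the titles' groups. Quantile normalization, eBayes without trend, the 1.5-fold minimum, cyclic loess and the replicate block with quantile normalization gave 0 probes when all were tested. Over bright probes alone, the unpaired fit gave 2 (2 higher) after quantile normalization and 2 (2 higher) after cyclic loess. The unpaired fit without the dimmest 50% gave 3 (3 higher), no scaling 3 (2 higher, 1 lower), and an offset of 50 gave 12 (11 higher, 1 lower). The replicate block gave 29 (27 higher, 2 lower), with cyclic loess 12 (11 higher, 1 lower) and without the dimmest 50% 9 (9 higher). Median centring and leaving out the dimmest 25% gave the same count as the main fit. Leaving out 1 array at a time gave 0 to 325 probes (0 to 185 higher, 0 to 140 lower). It was 0 without either CD66High array, 325 without CD66Low of set 1 and 147 without CD66Low of set 2. In these fits the lone array is assumed to vary like the other group, so that a value set by 1 array can pass, as GT_44k_23_P23171 did without CD66Low of set 1. It need not: GT_44k_24_P257478 did not pass without CD66High of set 1, at a log2 difference of 8.23. The assumption alone therefore does not tell why the counts differed between the arrays left out. Grouping by the CD66 characteristic gave 0 probes and a log2 difference of -3.96 for GT_44k_24_P257478, and the crossed groups gave 0 probes, -3.98 for GT_44k_24_P257478 and 3.96 for GT_44k_23_P23171. These reversals follow from which group holds the 1 high array. For the other changes the cause was not tested. The 367 probes at least 2-fold apart in both sets (317 higher, 50 lower) became 1343 at 1.5-fold (1175 higher, 168 lower), 259 after quantile normalization (152 higher, 107 lower), 294 after cyclic loess (229 higher, 65 lower), 64 without the dimmest 25% (45 higher, 19 lower) and 17 without the dimmest 50% (16 higher, 1 lower). Alternatives added after the data were seen are listed with the methods. Signal limits all of this: the within-group SD of the log2 values was 0.21 for bright and 0.47 for dim probes.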

Other observations

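The tests of all 3 patterns below were chosen after the results that prompted them were seen, those of the third before their correlations were computed and without the pair that prompted them.

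Probes at least 2-fold apart in both sets were mostly higher in CD66High cells. Of the dim probes (mean signal at or below the median), 301 were higher and 49 lower. Quantile normalization brought the higher ones to 56.2% of those probes (95% exact binomial interval 49.7 to 62.5, treating probes as independent), from 86.0%, and cyclic loess to 76.9% (213 of 277, interval 71.5 to 81.7). The dim probes of the crossed groups were also lopsided within both sets, with 62 higher and 123 lower. Cyclic loess made them more so, with 53 and 161, where quantile normalization gave 85 and 88. Whether that crossed imbalance is itself an artefact was not tested, so the 76.9% is not read for or against an offset between arrays. The median scaled log2 signal of the dimmest 25% of probes was -7.46 and -7.15 on the CD66High arrays and -7.61 and -7.83 on the CD66Low arrays. Whether an offset between arrays at low signal accounts for the dim part stays open, since quantile normalization gives every array the same distribution and could also even out a real excess. Among bright probes the higher ones stayed at 94.1% after either normalization (16 of 17, interval 71.3 to 99.9), while 14 bright probes were 2-fold apart in opposite directions. The 75th percentile scaling by itself makes the median scaled log2 signal of bright probes almost equal on every array. It ran from -0.00051 (CD66High, set 2) to 0.00049 (CD66Low, set 2). That range therefore does not show how much either normalization had to change among bright probes. How far an offset at low signal reaches into the bright probes was not measured, so the unchanged share does not test the offset there. A difference between the sorted cells remains open for the 16 higher bright probes. So does any handling step that differed between the sorted groups, which the design does not separate from CD66.

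The sets of experiments held more small p-values than the sorted groups. Unequal scaling of the arrays is argued against, since the ratio of the 2 counts was still 3.66 after quantile normalization (5217 and 1427 probes at an unadjusted limma p under 0.05). With the other factor as a block it was 1.92, and 2.34 after quantile normalization. The CD66 characteristic names the same split as the sets. Whether it or the titles hold the right groups cannot be told apart from a difference between the sets, because 0 probes have a gene name and the CEACAM probes could not be read. A difference in culture, labelling or hybridisation between the sets was not tested and stays open.

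Of the 16 bright probes higher in both sets, 2 in the HS series had consecutive numbers. This prompted the hypothesis that neighbouring numbers in that series measure related transcripts. Over the other 771 consecutive pairs with both members bright, the CD66High minus CD66Low log2 differences correlated at a Spearman's rho of 0.49 (permutation p = 0.0001, the smallest that 9999 permutations can give). Pairs along a run of numbers share probes, so the 771 pairs are not independent. The mean levels correlated at 0.58 and the differences between sets at 0.53. The rho was 0.47 after the trend of the difference on the mean level had been removed, which argues against a bias shared by probes of like level. The values are consistent with neighbours that target the same or related transcripts, in which case the 2 probes may count as 1 transcript. The positions of probes on the array were not used here, so that a spatial effect stays open.

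Single arrays stood far from the other 3 on a small number of probes. With the other 3 arrays within 2-fold of each other, 15 probes read at least 8-fold above them on the CD66High array of set 1, 13 on the CD66Low array of set 1, 51 on the CD66High array of set 2 and 30 on the CD66Low array of set 2. Of these, 1, 0, 1 and 1 were bright probes. The largest such excess was 2439-fold, on the CD66High array of set 1. Only 1 probe read at least 8-fold below the other 3, also on the CD66High array of set 1.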
